A study of Xenopus laevis with 6 samples.

How the data were processed

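Total RNA from dorsal marginal zone explants of Xenopus laevis gastrulae was hybridised, 1 sample per array, to 6 one-colour Agilent arrays. Per the labels, 3 samples came from embryos injected with a control morpholino (control MO) and 3 from embryos injected with a LEF1 morpholino (LEF1 MO), and the series design calls the samples of each group biological replicates. Replicates were numbered 1 to 3 in both groups.

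The authors deposited scanner output whose spot values are intensities on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. The processed intensity is background-corrected by that software, per the file headers. The deposited flags mark spots as well above background, saturated or an outlier. The authors also deposited a table of log2 values for the same arrays. Its column medians were 5.482516 in each control MO array and 5.482226 in each LEF1 MO array, and each column correlated with its own array's log2 scanner values across probes at 0.998 or above. Its scale is therefore log2, while how it was centred is not given in the sources used here. No column of that table lacked a sample.

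From the scanner files, log2 of the processed intensity was taken, control spots and outlier-flagged spots were left out, the 4 spots of each of 50 repeated probes were averaged, and each array's 75th percentile was subtracted. Of 43653 probes, 46 were left out because a flag left an array without a value. The 26964 probes well above background on all 3 arrays of at least 1 group were tested. A gene was represented by the probe with the highest mean over the 6 arrays, which gave 19216 genes. A RefSeq table of assembly Xenopus_laevis_v10.1 gave 16137 probes a symbol by accession and 678 by synonym. A further 2156 kept the name in the file and 24682 had no symbol. No coordinates were used.

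The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), as planned without a block. Each SE of a difference is limma's moderated SE, in which a gene's own variance is drawn toward that of all genes. It can thus be smaller or larger than an SE from the gene's own values alone. Gene lists were tested with limma's camera (preset correlation of 0.01), camera with an estimated correlation, and fry. The 20 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule named lef1, then up to 10 rises and 10 falls past the threshold on which every LEF1 MO array lay on one side of every control MO array, filled up to 5 with the smallest p where fewer than 5 passed, then up to 4 members per list that passed or up to 2 that did not. A gene's adjusted p was taken over the genes tested. The same rule was applied to the fit with the replicate block, a step chosen after the data were seen. Transcripts with no symbol are given by the description in the files, and placeholder symbols were not counted as names.

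Whether the replicate numbers pair the arrays was decided from the correlations below, by a rule set beforehand that each same-numbered pair must exceed 0.1. The count of calls with the block was printed in the same run, so it was not hidden when the decision was made. Deviations from the group means, taken across tested probes, correlated between same-numbered arrays at 0.69, 0.69 and 0.48, and between arrays of different numbers at -0.01 or below. Because deviations are centred within each group, positive values for the same numbers push the others below 0, so that contrast is partly built in. With so few replicates, few matchings of the arrays exist, and a match by chance cannot be excluded. The labels give no reason for the pairing. Same-numbered arrays were scanned in succession, the LEF1 MO array first each time. Pairing may thus follow processing order, and scan order within a pair cannot be told apart from group. Values of the fit with the replicate number as a block therefore stand beside the planned ones.

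On simulated data with the real spread and pair differences, 200 of 26964 probes were changed in each of 20 runs. Noise was drawn independently for each probe. With the block, 56.2% of the probes changed by 1 on the log2 scale and 99.7% of those changed by 2 were recovered. Without the block, which leaves the simulated pair differences in the error, none was recovered. With the block, 10.2% of all calls were false, which is more than the nominal share. Deviations that probes share beyond the pair differences were not simulated, so the false share in the real data may differ.

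Where a probe was not well above background on any array of a group, the fold is given as "at least": the mean of the brighter group over the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background. No spot was saturated on any array. The number of arrays limits the precision. An exact test of 3 against 3 arrays cannot give a p under 0.1.

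Each array lay on its own slide, so no slide block was possible. All control MO arrays lay at 1 position of their slides and all LEF1 MO arrays at another, so array position and group cannot be told apart. Alternatives were other background corrections and scalings, other filters, array weights, the deposited table, other variance settings, and each array left out. Alternatives kept with the block, the 3 replicates left out as pairs, and a correction for probe GC content were chosen after the data were seen. In the comparison of settings, the direction of a list was that of its camera test. This too was chosen after the data were seen, when 49 of 620 comparisons had turned by the list median; by the camera test 41 did.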

Results

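LEF1 is an HMG-box transcription factor that acts with beta-catenin in canonical Wnt signalling. The series set out to find genes that depend on it in the dorsal marginal zone, the tissue of the Xenopus gastrula that includes the Spemann organizer. Embryos received a control or a LEF1 morpholino, an antisense oligomer, in both dorsal blastomeres at the 8-cell stage. At stage 10.25 the explants were cut out, and they were then kept until sibling embryos had reached stage 12. RNA of 30 explants made up each of the 3 samples per group. Between 59.9% and 67.1% of the spots on an array were well above background. The array of LEF1 MO replicate 1 was the dimmest, with a 75th percentile of processed signal of 166, against 353 to 447 on the other 5 arrays.

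The lef1 transcript itself was not lower in LEF1 MO explants. Its brighter probe had values of -0.39, -0.65 and -1.05 in control MO replicates 1, 2 and 3, and of 1.15, -0.65 and -0.39 in LEF1 MO replicates 1, 2 and 3 (log2 signal relative to the array's 75th percentile). The difference was 0.73 ± 0.48 (SE, n = 3 per group; limma adjusted p = 0.63, and 0.21 with the replicate block). Without LEF1 MO replicate 1 it was 0.17. The second probe differed by 0.83 ± 0.52 (SE). Exact two-sided permutation tests gave p = 0.5 and p = 0.2. A morpholino can block translation without lowering the mRNA, so this level checks little about the labels.

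With each replicate's arrays compared as a pair, the caveolin gene cav1, the carbonic anhydrase gene ca2, the ciliary gene tekt2 and the collagen gene col2a1 were among the genes that fell in LEF1 MO explants, and the maternal gene zar1 and the GATA factor genes gata4 and gata5 among those that rose. Of 19216 genes, 330 changed with the replicate block (limma adjusted p under 0.05), 75 upward and 255 downward. With normexp background correction the balance over calls of any size turned, and 55.2% of 1569 changed genes were higher, against 22.7% here. By probe, 410 of 26964 changed and 408 of these by at least 2-fold, 92 upward and 316 downward. At that size most calls stayed downward with normexp. There 27.5% of 385 probes changed at least 2-fold were higher, against 22.5% of the 408. In the planned fit without the block, limma called 0 probes and 0 genes, with 2676 probes at an unadjusted p under 0.05, and the smallest adjusted p was 0.17. The blocked count ranged from 0 to 2412 probes over the alternatives. It was 116 without replicate 1, 1159 without replicate 2 and 0 without replicate 3.

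**Figure D1:**
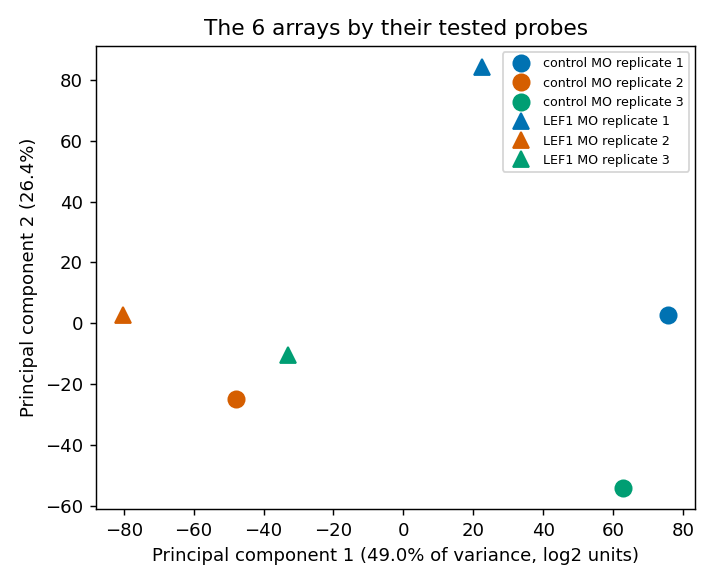
The first 2 principal components of the 26964 tested probes, in log2 units, with 1 point per array, circles for control MO, triangles for LEF1 MO and a colour per replicate number. Component 1 holds 49.0% of the variance and separates both replicate 2 arrays and LEF1 MO replicate 3 from the other 3 arrays.

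The largest falls and rises were taken among genes with a symbol or description and no overlap of values between the groups, as for 99 of the 255 falls and 27 of the 75 rises. By mean signal the 10 largest of these falls included the caveolar coat genes cav1, cav-3 and cavin1. Of the 10, 6 were not well above background on any LEF1 MO array, so their order rests on signals near background. The cav1 gene, which encodes caveolin 1, fell by 3.29 ± 0.27 on the log2 scale (moderated SE, 3 pairs; adjusted p = 0.020). The SD between its 3 pair changes was 0.65. The muscle caveolin gene cav-3 fell by 3.47 ± 0.23 (SE; adjusted p = 0.015), from 1.96 ± 1.26 to -1.51 ± 0.98 (SD, n = 3). The signal of cavin1 was not well above background on any LEF1 MO array and was at least 6.21-fold lower there (adjusted p = 0.022). Ionocytes are ion-transporting epidermal cells that carry carbonic anhydrase and proton pumps. Carbonic anhydrase ca2 fell by 3.52 ± 0.28 (SE; adjusted p = 0.019) and was well above background on 2 of 3 LEF1 MO arrays. The proton pump subunits atp6v1b1 and atp6v0a4 were at least 3.93-fold and 5.24-fold lower (adjusted p = 0.015 and 0.047). The remaining falls were spaca9 (at least 3.36-fold), col8a1 (10.6-fold, with an SE of 0.49 on the log2 scale, above background on 2 of 3 LEF1 MO arrays), a transcript described as a probable G-protein coupled receptor (at least 9.82-fold) and one described as a multiple myeloma tumor-associated protein (at least 6.31-fold). In the fit without the block, these 10 had adjusted p of 0.24 to 0.42.

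The 10 largest of the 27 rises were led by bcl11a, a zinc finger gene, at 2.74 ± 0.36 (SE; adjusted p = 0.039; above background on 2 of 3 control MO arrays). The RNA-binding protein gene rbpms2 rose by 2.60 ± 0.26 (SE; adjusted p = 0.023), with all 4 of its probes higher. The forkhead gene foxr1 rose by 1.88 ± 0.19 (SE) and zar1, a maternal gene of the oocyte, by 1.76 ± 0.17 (SE; adjusted p = 0.023 and 0.022). The other 6 of these 10 lay between 1.46 and 1.75. They were menf.1 (above background on 2 of 3 control MO arrays), gramd2b, washc3, and transcripts described as an oocyte zinc finger protein, a D930010j01rik-prov protein and a CD276 antigen homolog.

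No gene passed in the planned fit (smallest adjusted p over all genes 0.13, for a transcript with no symbol or description), so the 5 smallest p in each direction among genes with either are given as values. The higher ones were gramd2b at 1.53 ± 0.22, rrm2b at 1.21 ± 0.20, rbpms2 at 2.60 ± 0.48, the histone gene h4c1 at 2.43 ± 0.44 (above background on 2 of 3 control MO arrays) and a transcript described with a dehydrogenase E1 and transketolase domain at 1.13 ± 0.21 (SE, n = 3; adjusted p of 0.23 to 0.32). The lower ones were ehd2, cbx8, tspan18, a glutamine synthetase transcript and an adenosine deaminase transcript, all with adjusted p = 0.23. On no LEF1 MO array were the first 4 well above background, and they were at least 4.43-fold, 1.45-fold, 1.87-fold and 1.37-fold lower. The adenosine deaminase transcript differed by -2.14 ± 0.22 (SE; above background on 2 of 3 LEF1 MO arrays). With normexp background correction, cbx8, tspan18, the glutamine synthetase transcript and col1a1 turned to slightly positive differences.

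**Figure D2:**
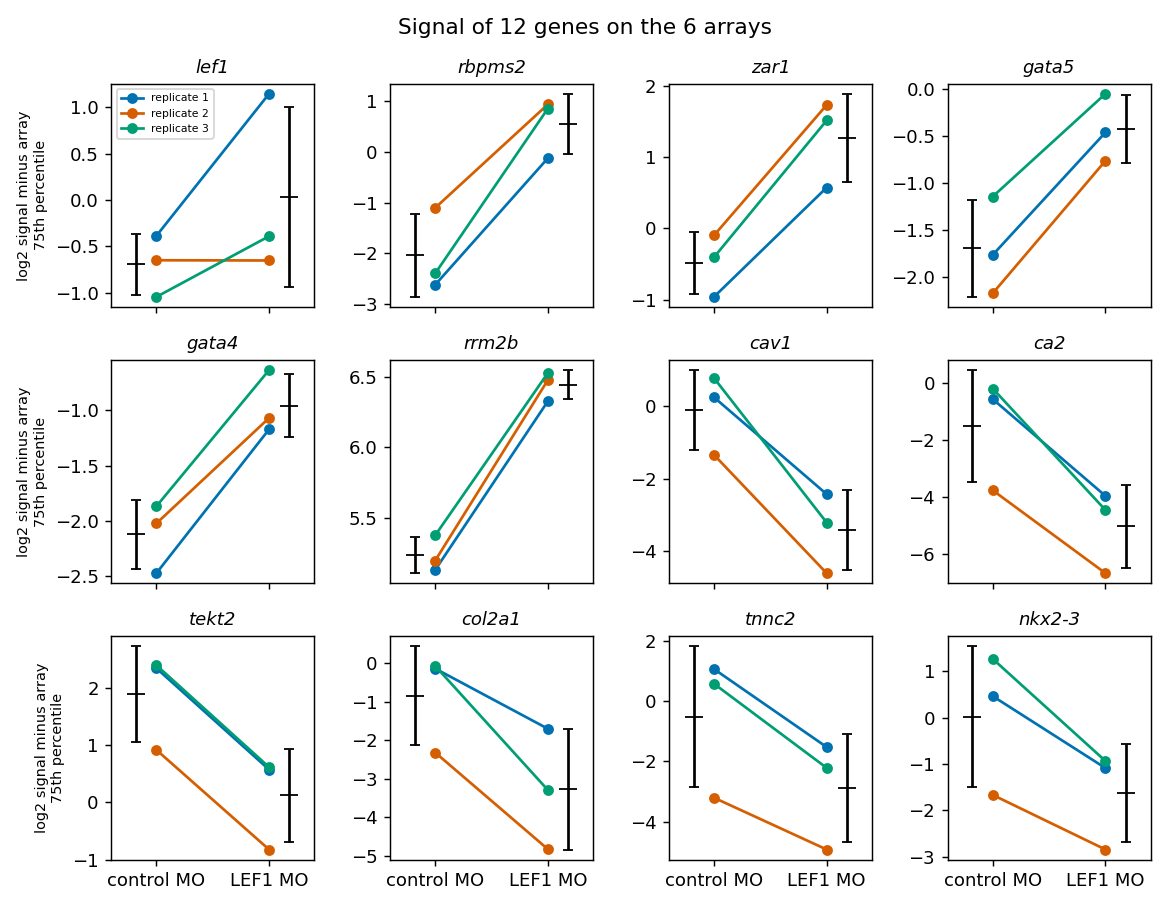
Signal of 12 genes on each array (log2 signal minus the array's 75th percentile), with a line joining the arrays of each replicate number and black bars for the group mean ± SD (n = 3). lef1 is higher in LEF1 MO replicates 1 and 3 and level in replicate 2, and the other 11 genes move the same way in all 3 pairs.

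Of the 20 fixed gene lists, 0 shifted in the planned fit (camera smallest adjusted p = 0.11; 0.90 with an estimated correlation). With the replicate block 1 shifted. Paraxial mesoderm and muscle genes were lower, with a median of -0.43 over 32 measured members (adjusted p = 0.0032), and pair medians of -0.67, 0.01 and -0.48. The adjusted p was 0.80 in camera with an estimated correlation, so the call depended on the preset correlation. With the block that test rests on 2 residual degrees of freedom and has little power. It therefore does not show that the list was unshifted. Of its members only tnnc2, a fast troponin C gene, changed over all genes tested, and fell by 2.37 ± 0.25 (SE; adjusted p = 0.024). Adjusted over the list alone, 1 member was higher and 4 were lower. In the planned fit tnnc1 differed by -1.04 ± 0.41 and hes7.1 by 1.19 ± 0.27 (SE), without passing.

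Among extracellular matrix and adhesion genes (median -0.17, 40 measured), 4 fell and 0 rose with the block, and 9 fell and 3 rose adjusted over the list alone. The collagen gene col2a1, of notochord and cartilage, fell by 2.43 ± 0.32 (SE; adjusted p = 0.040) and col9a1 by 1.38 ± 0.19 (SE; adjusted p = 0.043). Values of col2a1 overlapped between the groups, and its SE in the planned fit was 0.90 (limma adjusted p = 0.47). The lysyl oxidase gene loxl2 fell by 2.65 ± 0.31 (SE; adjusted p = 0.032; above background on 1 of 3 LEF1 MO arrays), and col1a1 was at least 2.005-fold lower. Among epidermis and ciliated cell genes (median 0.01, 30 measured, camera direction down), 3 fell and 0 rose with the block, namely ca2, atp6v1b1 and the ciliary gene tekt2, by 1.77 ± 0.15 (SE; adjusted p = 0.020), and 5 fell adjusted over the list alone. Keratin krt19 differed by -1.36 ± 0.25 (block SE) without passing.

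Among endoderm genes (median 0.28, 21 measured), gata5 rose by 1.27 ± 0.16 (SE; adjusted p = 0.039) and gata4 by 1.16 ± 0.16 (SE; adjusted p = 0.043) with the block, and adjusted over the list alone 5 were higher and 1 was lower. Among blood, endothelial and cardiac precursor genes (median 0.05, mean -0.32, 16 measured), gata4 rose and nkx2-3 fell by 1.64 ± 0.23 (SE; adjusted p = 0.043), and adjusted over the list alone 1 was higher and 6 were lower. Germ plasm and vegetal maternal genes had a median of 0.27 over 23 members, of which zar1 rose. In the p53 response list (median 0.27, 27 measured), rrm2b, a ribonucleotide reductase subunit, rose by 1.21 ± 0.15 (SE; adjusted p = 0.038). In the cell cycle list (median 0.21, 66 measured), rrm1, another subunit, rose by 1.199 ± 0.19 (SE; adjusted p = 0.049). The posterior gene hoxb9 was at least 2.18-fold lower (adjusted p = 0.046) and was the 1 member that passed among neural plate genes (median -0.02, 42 measured) and among ventrolateral and posterior mesoderm genes (median 0.09, 37 measured). Values of nkx2-3, rrm1 and hoxb9 overlapped between the groups. In the planned fit their SE were 0.83, 0.41 and 0.79 (limma adjusted p = 0.54, 0.45 and 0.50). In the notochord and trunk organizer list (median 0.15, 14 measured) col2a1 was the 1 member that passed. Adjusted over the list alone, mos, zp2 and zar1 were higher among germ plasm genes, rrm2b and ei24 higher and mdm4 lower among p53 response genes, and hoxb9 and tubb2b lower among neural plate genes.

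No member passed over all genes tested in either fit in the other lists. Canonical Wnt/beta-catenin target genes, the list closest to the question of the series, had a median of 0.22 over 40 measured members (camera adjusted p = 0.59 in both fits). Their smallest p belonged to apcdd1, at -0.76 ± 0.19, and en1, at -0.78 ± 0.17 (block SE; adjusted p = 0.10 and 0.087). Wnt pathway components had a median of 0.15 over 60 members, with fzd4 at 0.81 ± 0.16 and csnk1g1 at 0.70 ± 0.15 (block SE). Medians were 0.15 over 37 convergent extension and planar cell polarity genes, 0.22 over 15 head organizer and prechordal genes, 0.24 over 42 BMP and Nodal signalling genes and 0.20 over 29 FGF signalling genes. They were 0.16 over 20 Notch signalling genes, 0.13 over 28 neural plate border and neural crest genes, and 0.08 over 21 innate immune and interferon genes. The organizer gene cer1 differed by 1.298 ± 0.27 (block SE; adjusted p = 0.077). Adjusted over the list alone with the block, hes7.1 and rfng were higher among Notch genes and flrt2 lower among FGF genes. In fry's test of change in either direction, p53 response genes had an adjusted p of 0.024 in the planned fit but 0.063 with the block. With the block, matrix, epidermis and endoderm genes had 0.041 and Notch genes 0.048. In the planned fit these lists did not pass, at 0.18, 0.50, 0.42 and 0.077 in that order.

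**Figure D3:**
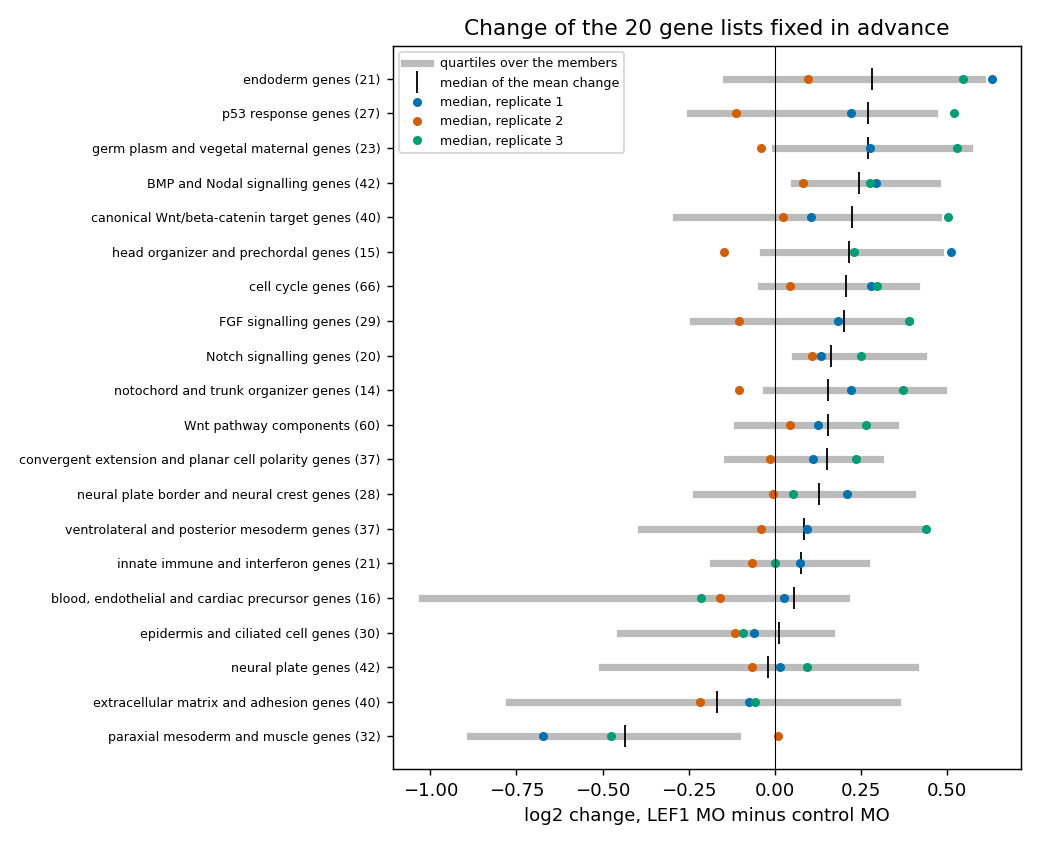
Median log2 change of the 20 lists (LEF1 MO minus control MO; number of measured members in brackets), with grey bars from the lower to the upper quartile, black ticks for the median of the mean change and coloured points for the median in each replicate pair. Paraxial mesoderm and muscle genes have the lowest median, -0.43, with 0.01 in replicate 2.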

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

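Without a block, the counts of changed probes, genes and probes changed at least 2-fold stayed at 0 in all planned settings but 2. With array weights they were 185, 262 and 185, and with the replicate block 410, 330 and 408. Left out one array at a time, the counts stayed at 0. The number of shifted lists was 0 as planned, 2 with normexp background correction, 3 with no filter, 1 with probes well above background on all arrays, 4 with array weights and 1 with the replicate block. It ranged from 0 to 5 when 1 array was left out, with 5 without LEF1 MO replicate 1 and 4 without control MO replicate 2. The lef1 difference kept its sign and stayed short of the threshold in every setting run. It ranged from 0.17 to 1.07. A slide block was not run, because each slide holds 1 array. Normexp and no filter moved the median over all probes to 0.13, against 0.04 as planned. The replicate block took 17 of the 48 genes named by the planned fit past the threshold, where none had passed, and 1 list, paraxial mesoderm and muscle genes. In fry's test of change in either direction it also ended the call of p53 response genes and added those of matrix, epidermis, endoderm and Notch genes. Counts adjusted over a list alone changed as well.

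All settings combined with the block were chosen after the data were seen. With the block, the count of probes, of genes and of probes changed at least 2-fold depended strongly on the setting. They were 2369, 1569 and 385 with normexp, of which 55.2% of probes were higher, against 22.7% in the blocked fit itself. Of the probes changed at least 2-fold, 27.5% were higher with normexp, against 22.5% in the blocked fit itself. The 3 counts were 170, 202 and 170 with quantile normalization, 170, 204 and 170 with the deposited table, and 680, 491 and 649 with median scaling. With no filter all 3 were 0, and with probes well above background on all arrays they were 712, 542 and 573. They were 2412, 2018 and 1077 with a trended and robust variance, of which 45.9% of probes were higher. At an adjusted p under 0.1 there were 2039 probes and 1543 genes, and 0 of either with the unmoderated test, with 2 residual degrees of freedom. With whole replicates left out, probes ranged from 0 to 1159, genes from 0 to 986, probes changed at least 2-fold from 0 to 1159, and lists from 0 to 5. The lowest count of probes and genes came without replicate 3 and the highest without replicate 2. The number of lists was 2 with normexp, quantile normalization, no filter and the deposited table, and 0 with an estimated correlation. The cause of these changes was not tested. No filter adds probes near background to those tested. Fewer arrays leave fewer residual degrees of freedom, but this alone cannot give both 1159 probes without replicate 2 and 0 without replicate 3.

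Among named genes, the difference of cbx8 turned to 0.037, col1a1 to 0.12, the glutamine synthetase transcript to 0.065 and tspan18 to 0.076 with normexp, in both fits, and eif2ak2 to -0.53 without control MO replicate 1. No called list turned. The test direction of uncalled lists turned in 41 of 620 comparisons, the smallest adjusted p being 0.33. Their medians with normexp were 0.16 for Wnt target and 0.16 for FGF genes, 0.11 for convergent extension and 0.11 for neural border genes, 0.044 for neural plate, 0.22 for notochord and 0.15 for ventrolateral genes. With no filter they were 0.15 for convergent extension, -0.072 for neural plate, 0.13 for notochord and 0.085 for ventrolateral genes with the block, which was also the value with the mean of all probes. With array weights they were 0.0038 for neural border, -0.043 for neural plate and -0.013 for ventrolateral genes. Neural plate genes were at -0.032 with quantile normalization, -0.027 with the deposited table and -0.020 with the replicate block, and blood genes at 0.073 with the stricter filter. When 1 array was left out, medians ranged from -0.37 to 0.073 for blood, 0.016 to 0.35 for Wnt target, -0.048 to 0.35 for FGF, 0.0030 to 0.17 for innate immune, -0.14 to 0.28 for neural border, -0.14 to 0.17 for neural plate, 0.048 to 0.29 for notochord and -0.22 to 0.45 for ventrolateral genes, and the difference of eif2ak2 ranged from -0.53 to 1.69. When whole replicates were left out of the blocked fit, they ranged from 0.058 to 0.44 for head organizer, -0.0049 to 0.18 for neural border and -0.022 to 0.21 for ventrolateral genes.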

Other observations

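The lists in this part, apart from epidermis, were written after the data were seen, and so were all tests except the counts over other splits. The early gastrula list and its prediction were written before the values of that list were looked up, but after other data were seen.

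Lists of motile cilia and basal body, ionocyte, caveola, and oocyte and blastula genes were drawn up from the calls, so neither their counts nor their medians are independent evidence. In camera with an estimated correlation none passed (adjusted p of 0.17, 0.14, 0.12 and 0.29 with the block), a test with little power at 2 residual degrees of freedom. Of 55 measured cilia genes 52 had negative differences, with a median of -0.84 and pair medians of -1.17, -0.53 and -1.0. With the replicate block 14 fell (limma adjusted p under 0.05), among them tekt3 by 2.35 ± 0.33 (well above background on 2 of 3 LEF1 MO arrays), spag6 by 1.97 ± 0.18 and ccdc78 by 1.94 ± 0.18 on the log2 scale (SE, 3 pairs), and 0 in the planned fit. Of 11 ionocyte genes 5 fell and of 10 caveola genes 5, with medians of -1.54 and -1.30. Oocyte and blastula genes had a median of 0.88 over 24 members, with pair medians of 0.81, 0.19 and 1.38, of which 4 rose, among them pou5f3.3, a pluripotency factor gene, by 2.48 ± 0.38 (SE).

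For the cilia and ionocyte genes as one set (66 measured, median -0.85, quartiles -1.30 and -0.47), probe GC content, the dim array and less epidermis were weighed as the whole cause. The median was -0.86 after a correction of each array for probe GC content, which argues against GC content as the whole cause. It was at most -0.56 in replicates 2 and 3. The lists were drawn up from the calls, however, which favour genes that fall in all 3 pairs. The medians in replicates 2 and 3 therefore do not decide on the dim array of LEF1 MO replicate 1. Less epidermis as a whole would lower other epidermal genes too, but the median of 22 epidermal genes in neither list was 0.099, with quartiles of -0.31 and 0.25. Among these 22 the abundant itln1 (-1.17), krt19 (-1.36) and krt12.4 (-0.46), picked after their values were seen, were lower in all 3 pairs and krt70 (0.13) was not, so fewer of some epidermal cells stays open. Slower development of LEF1 MO explants was not decided: the same genes were lower in replicate 2 than in the mean of replicates 1 and 3 within each group, by medians of -1.14 in control MO and -0.67 in LEF1 MO, but no outcome of that comparison would have counted against it, so it stays open. An effect of LEF1 itself was not tested and stays open too. With the block 14 of 55 cilia and 5 of 11 ionocyte genes fell, and the regulator genes among the members did not pass. These were foxj1 (0.13), myb (0.35), rfx2 (-0.11), mcidas (-0.43), ccno (-0.42), foxi1 (-0.41) and ubp1 (-0.38). Of these, mcidas, ccno and ubp1 were lower in all 3 pairs and the others were not. Most other members did not pass either, so the regulators are not shown to be spared. A loss of the cells that carry the cilia and ionocyte transcripts and lower levels within those cells cannot be told apart here. Which cells of the explants carried these transcripts was not determined.

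Across 19216 genes, which are not independent replicates, the change in a pair was correlated with the difference between the other 2 replicates, on arrays it shares none with, in pairs 1 and 3. In control MO and in LEF1 MO arrays the correlations were 0.40 and 0.11 for pair 1 (with replicate 2 minus 3), 0.05 and -0.09 for pair 2 (with 1 minus 3), and -0.54 and -0.34 for pair 3 (with 1 minus 2). The changes of pairs 2 and 3 correlated at 0.52, which argues against the dim array as the source of the shared change, while the groups share 0 array positions, so array position and the LEF1 morpholino cannot be told apart. Scan order within a pair cannot be separated from the morpholino either. Slower development, by which replicate 2 and LEF1 MO explants would be younger, could give this pattern and was tested on genes that decline during gastrulation (15 of 26 measured). Of these, bix1.1, gdf3, nodal and vegt are also in the oocyte and blastula list drawn up from the calls, so the test is not fully independent of them. The median of the 15 was 0.46, with 0.58, -0.040 and 1.01 in pairs 1, 2 and 3. The predicted median over 0 in every pair was thus missed in pair 2, the outcome written beforehand as counting against the hypothesis. The miss was smaller than the spread of the members in that pair, so the hypothesis was left open, as was an effect of LEF1 itself.

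Other splits of the arrays were too few for a share under 0.05. In the planned fit the real split and the other 9 of the 10 splits gave 0 changed probes, 0 changed genes and 0 probes changed at least 2-fold, so all 10 gave as many. Shifted lists numbered 0 in the real split and up to 8 in the others. The splits with 7 and 8 kept 2 replicate pairs together, but whether the pair structure is the cause was not tested. Of the 3 other splits that part all 3 pairs, 1 gave 4 lists and 2 gave 0. With the replicate block, the real arrangement gave 410 probes, 330 genes and 408 probes changed at least 2-fold, and 1 of the 4 arrangements of labels within the pairs, the real one, gave as many, with 0 as the highest of the others. For lists, 3 of the 4 arrangements gave as many as the real 1, and the highest other gave 7.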
